A study of Saccharopolyspora spinosa with 4 samples.

How the data were processed

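Total RNA was sequenced from mycelium of wild-type *Saccharopolyspora spinosa*, a soil actinomycete that makes the insecticidal spinosyns. Per the labels, the untreated strain Sas001 was grown as a stationary culture on agar and RNA was taken at 24, 36, 48 and 72 h. Each time point was 1 library, so there were 4 libraries, no replicates and no control samples. The series design text speaks of fewer time points than the 4 that are listed, and all 4 were used. Column names of the table carry the prefix SP5, which the labels do not explain, and were matched to samples by the time in each name.

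The authors deposited 1 table of 7560 genes with a raw count and an FPKM value per gene and library, per the file headers. The submitters' processing notes name fastp, a read trimmer, and Bowtie2, an aligner, with no version. The program that made the counts, whether it used strand, how it treated reads that align to several places and the genome build were not given in the sources used here. The FPKM values deposited by the authors were recomputed here as the count divided by the length of the locus and by the total of the counts, and differed from that by at most 0.0023% among values with a count above 20. The table gives each gene's start and end on 1 chromosome record but no strand. Because neighbouring genes can overlap and strand was not known, reads from a gene and from a transcript antisense to it could not be separated. The locus length was a multiple of 3 for all but 64 genes.

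Counts were the values used, and the FPKM values served as an alternative. Library totals were 16115121, 13793850, 10749336 and 12769627 counts at 24, 36, 48 and 72 h. Libraries were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.14, 1.04, 0.974 and 0.867. A scaled CPM, the unit used throughout, is a count relative to the total times that factor. Relative to plain totals, TMM moved the median log2 ratio to 24 h by 0.14 at 36 h, 0.23 at 48 h and 0.40 at 72 h, so all changes are relative to that choice. Log2 ratios were taken after adding 1 scaled CPM, which understates the change of low genes. Folds are ratios of scaled CPM with nothing added.

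A gene passed the expression minimum with at least 10 scaled CPM in at least 1 library, and 4762 genes did. A pair of single libraries has no residual degrees of freedom, so the comparisons carry no p-value, and a trend over the 4 times was not fitted. Genes were counted by size, at an absolute log2 ratio of at least 2 (4-fold). For single genes the 95% interval of a level is the exact Poisson interval of its count, and that of a fold is the conditional Clopper-Pearson interval of a pair of counts. These intervals, and the floor of 3 counts that a count of 0 allows (0.163, 0.210, 0.287 and 0.271 scaled CPM at 24, 36, 48 and 72 h), cover counting error only. They say nothing of the variation between cultures. Later times were compared with 24 h, and 48 h with 36 h and 72 h with 48 h.

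Of 25 gene lists fixed before the data were examined, 24 had members that passed the minimum. They were CRISPR-Cas, rhamnose supply, acyl-CoA supply, polyketide and nonribosomal peptide synthases, ribosomal proteins, tRNA synthetases, RNA polymerase core, ATP synthase, respiratory chain, tricarboxylic acid cycle, glycolysis, chaperones, oxidative stress, sigma factors, development and sporulation, cell division and wall, recombination and end joining, restriction-modification and toxin-antitoxin, mobile elements, phosphate and nitrogen, iron and siderophores, secreted hydrolases, sugar transport, and amino acid and peptide transport. No gene was named as spinosyn biosynthesis in the table, so that list had 0 members and its genes were not analysed here as a group. Whether the polyketide synthase and deoxysugar genes described belong to it was not worked out here. Members were found by symbol and product name, and 12 matches whose description named another protein were removed after the data were seen. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value.

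Genes named in the report followed a rule fixed at the same time. It took every CRISPR-Cas gene, and for each comparison with 24 h the 10 largest rises and 10 largest falls among genes that passed the minimum and the 4-fold size, had a mean level in the upper part of genes passing the minimum (above the median) and had a symbol or product. It also took 2 to 4 members per list, from those with the largest change and the highest mean level, and the change was taken at 72 h. A description that gave only an organism or a contig was not treated as a product. A symbol or product was given for 4022 genes, a symbol for 693, and no description for 2730.

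The procedure was tested on simulated counts for 72 h against 24 h with 200 changed genes. All other genes kept the same mean level in every library, whereas in the data 1119 genes passed the 4-fold size at 72 h. The simulation therefore does not test the scaling under so broad a change, or the variation between cultures. With Poisson counts, 0% of 68 genes set to 2-fold, 23.8% of 63 genes set to 4-fold and 98.6% of 69 genes set to 8-fold were called 4-fold different, among 4478 genes run, and 0 of 4285 unchanged genes were. With negative binomial counts of dispersion 0.1 the shares were 8.82%, 41.3% and 89.9% among 4654 genes, and 17 of 4459 unchanged genes were called. Of 200 unchanged lists of 40 genes, 4.50% fell in the outer 5% of random lists, and a list lowered 2-fold lay at percentile 0. The unchanged lists were themselves random draws of independently simulated genes, so a share near 5% follows from the design. Neighbours that change together, as in some of the real lists, were not simulated, so this says nothing of how often their percentiles are extreme. Alternatives were the total count, DESeq2 1.42.0 size factors, totals without the 10 most abundant genes, FPKM, a pseudocount of 0.1 or 5, no minimum or one of 50, and a 2-fold or 8-fold size. Calculations and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.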

Results

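Gene expression in *Saccharopolyspora spinosa* mycelium was followed in 4 libraries, 1 each at 24, 36, 48 and 72 h of culture, so no difference below has a replicate check. Totals ran from 10749336 to 16115121 counts, and genes that passed the expression minimum had a median of 444 to 756 counts per library. The most abundant transcripts included ssrA, the transfer-messenger RNA that frees stalled ribosomes, at 7.27% to 8.71% of all counts, and rnpB, the RNA of ribonuclease P, at 3.92% to 7.86%. The 10 most abundant genes together took 20.3% of the counts at 24 h and 26.5% at 48 h. Of the 7560 genes, 678 had no count in any library, and 580 of those lay in a single span of 584 neighbouring genes at 6345536 to 7149396 on the chromosome. That span held 9 counts over the 4 libraries and included the urease genes ureC and ureG and the chaperone gene htpG. Whether these genes were absent, left out of counting or silent without background counts could not be told.

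**Figure D1:**
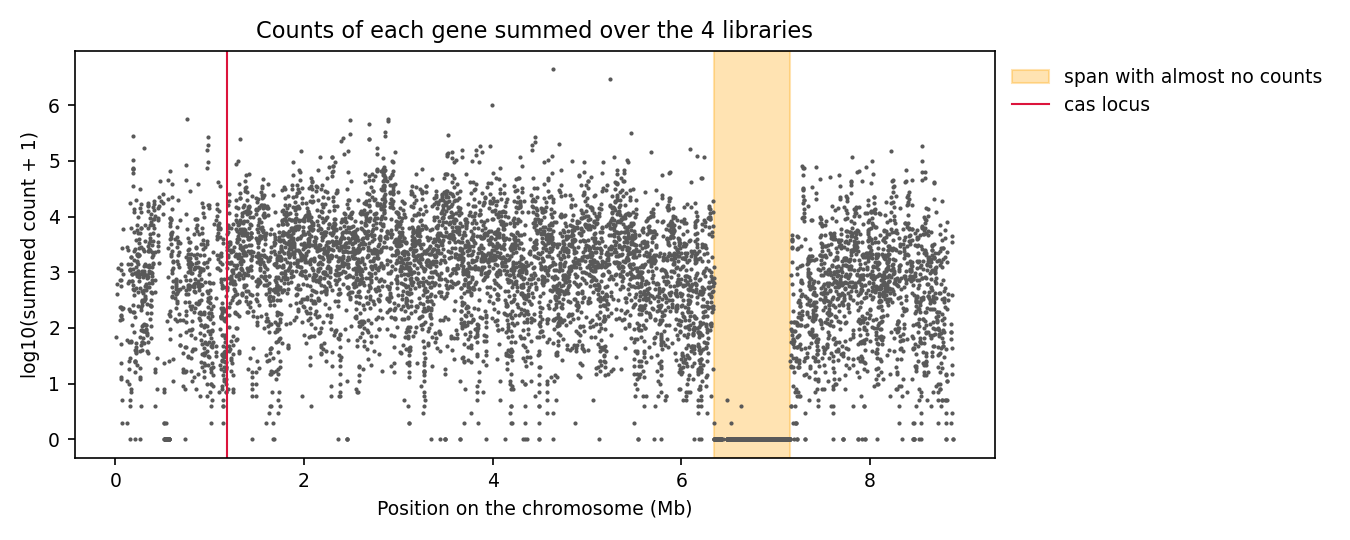
Each point is 1 of the 7560 genes, with its start on the chromosome (Mb) on the x axis and log10 of its count summed over the 4 libraries, plus 1, on the y axis. The shaded span of 584 genes held 9 counts in all, and the vertical line marks the cas locus.

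The stated purpose of the series was to see how the bacterium's own Type I-B CRISPR-Cas genes are transcribed. These genes encode an RNA-guided defence in which Cas1, Cas2 and Cas4 take part in acquiring new spacers, Cas5 and Cas7 belong to the complex that carries the guide RNA, and Cas3 is the helicase and nuclease that degrades the target. The table places cas2, cas1b, Cas4, Cas3, cas5 and cas7i next to each other at 1181717 to 1187581, followed by the undescribed genes IAG28_RS04165 and IAG28_RS04170 up to 1189736. Gaps between these 8 genes were 3 bp or overlaps of 4 bp. A second cas1 gene (IAG28_RS25315) lay apart at 5585368 to 5586885. All 9 genes had counts at every time. At 24 h Cas3 (IAG28_RS04150) was the highest of them, at 115 scaled CPM (95% interval 109.8 to 119.6), which placed it at percentile 83.5 of all genes. It was followed by IAG28_RS04165 at 82.2, cas1b (IAG28_RS04140) at 44.8, cas5 (IAG28_RS04155) at 39.0 and cas7i (IAG28_RS04160) at 32.1 scaled CPM. The lowest were IAG28_RS04170 at 15.7, the separate cas1 at 15.5, Cas4 (IAG28_RS04145) at 11.1 and cas2 (IAG28_RS04135) at 8.42. Scaled CPM is not corrected for gene length, so this order and the percentile depend on length, with Cas3 at 2451 bp and cas2 at 264 bp. By FPKM, which divides by length, cas5 was the highest at 24 h, at 68.1. IAG28_RS04165 followed at 64.8, Cas3 at 53.4, cas1b at 52.1, cas2 at 36.4 and cas7i at 35.8. The separate cas1 was the lowest, at 11.7.

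At 36 h the genes at the cas2 end of the locus were higher than at 24 h and those at the other end were lower. cas1b was 1.70-fold higher (95% interval 1.56 to 1.87), cas2 1.68-fold higher (1.35 to 2.08) and Cas4 1.31-fold higher (1.07 to 1.59). cas7i was 1.32-fold lower (1.16 to 1.51), IAG28_RS04165 1.49-fold lower (1.37 to 1.62) and IAG28_RS04170 1.62-fold lower (1.31 to 1.99). The interval of cas5 included no change, with a log2 ratio of −0.12. The log2 ratio of Cas3 was 0.14, but −0.0026 with total count scaling and −0.0025 with FPKM, so its direction depended on the scaling. The separate cas1 was 1.40-fold higher (1.18 to 1.65).

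From 36 h on, every gene of the locus and the separate cas1 had a lower level at each later time. The interval of each step excluded no change, except for IAG28_RS04170 at 72 h against 48 h. That gene had 49 counts at both times and a fold of 0.946 (0.623 to 1.43). Cas3 was at 126 scaled CPM at 36 h, 60.9 at 48 h and 28.8 at 72 h, and its percentile among all genes went from 85.0 to 62.2. Those are all 7560 genes, of which 2798 did not pass the minimum, so its place among expressed genes is lower. cas1b was at 76.3, 41.0 and 16.9 scaled CPM at those times. Against 24 h, the level at 72 h was 4.55-fold lower for cas7i (3.59 to 5.84), 3.98-fold lower for Cas3 (3.53 to 4.49), 3.69-fold lower for cas5 (3.03 to 4.53) and 2.65-fold lower for cas1b (2.26 to 3.12). It was 2.16-fold lower for Cas4, 1.98-fold lower for cas2 and 2.32-fold lower for the separate cas1. IAG28_RS04165 was 4.64-fold lower, and cas7i and IAG28_RS04165 were the genes of this locus past the 4-fold size. With total count scaling Cas3 and cas5 were past it as well, and with FPKM also IAG28_RS04170. The median log2 ratio of the 6 named genes of the locus to 24 h was 0.25 at 36 h, −0.69 at 48 h and −1.57 at 72 h, the last a 2.98-fold lower level. Over all 8 genes of the locus it was 0.01, −0.93 and −1.71, and that at 36 h turned to −0.13 with total count scaling, so the locus as a whole had no clear direction at 36 h. With the separate cas1 included, the list of 7 lay at percentile 81.2, 20.1 and 2.99 of matched random lists. Of these 7 genes 6 are neighbours, so the list holds fewer separate observations than members and its percentiles can look too extreme. Neighbours that overlap can share reads at their ends, and cas2 and Cas4 rested on 47 and 57 counts at 72 h.

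**Figure D2:**
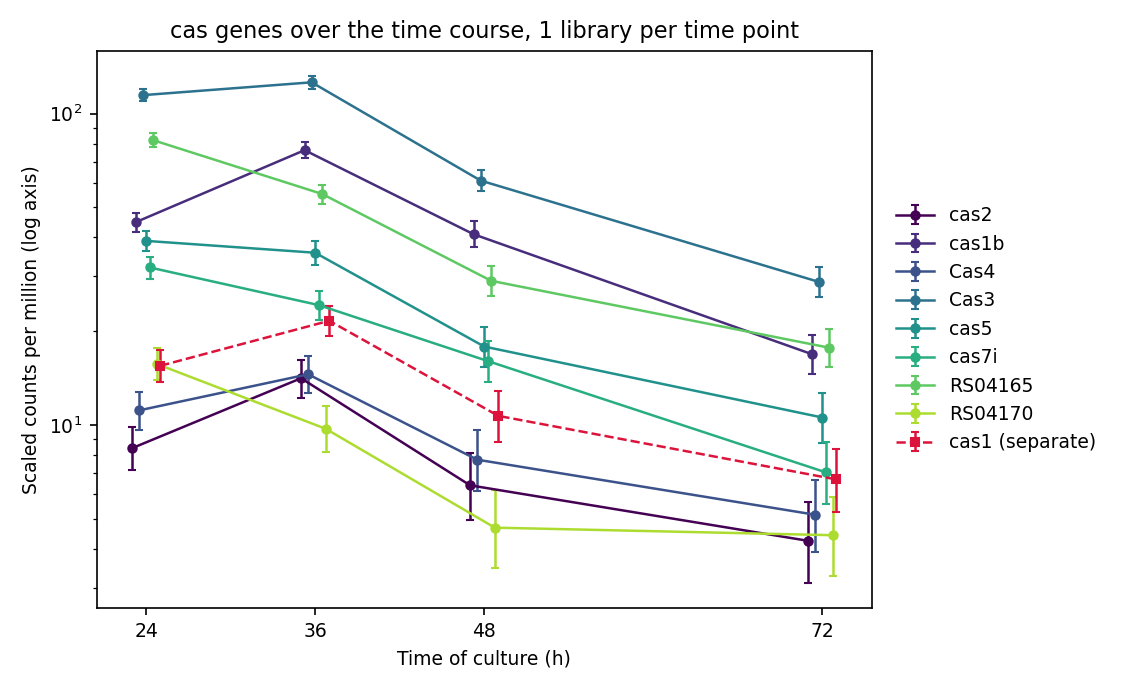
Scaled CPM (log axis) of the 8 genes of the cas locus (circles, coloured in chromosomal order) and of the separate cas1 gene (squares, dashed) against time of culture in h. Bars are 95% Poisson intervals of the count, points are shifted sideways for clarity, and Cas3 goes from 126 at 36 h to 28.8 at 72 h.

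At 36 h against 24 h, 225 genes were at least 4-fold higher and 112 at least 4-fold lower, 7.08% of the 4762 genes that passed the minimum. The largest rise among the named genes was IAG28_RS11240, an inhibitor of secreted subtilisin-type proteases, from 7.17 to 428 scaled CPM (59.6-fold, 95% interval 50.2 to 71.4). rocD, the ornithine aminotransferase of arginine and ornithine breakdown, was 32.3-fold higher (27.9 to 37.6). The gene IAG28_RS26030, described as a histamine oxidase, was 31.0-fold higher. Cytochrome bd oxidase, a terminal oxidase with a high affinity for oxygen, was higher through both subunits, IAG28_RS15680 by 24.7-fold and cydB by 22.7-fold, together with the neighbouring ABC transporter IAG28_RS15695 by 24.6-fold. IAG28_RS18935, a resuscitation-promoting factor RpfB, was 26.3-fold higher and the copper transporter IAG28_RS26800 21.7-fold higher. The adjacent genes IAG28_RS03290 (3-hydroxyacyl-CoA dehydrogenase) and IAG28_RS03295 (AMP-binding protein) were 16.9-fold and 16.3-fold higher and already at 136 and 279.8 scaled CPM at 24 h.

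Several of the named genes with the largest falls at 36 h were neighbours. Around the mycofactocin genes, which make a redox cofactor of actinobacteria, the electron transfer flavoprotein gene IAG28_RS04195 was 14.7-fold lower (12.8 to 16.9), mftF 7.16-fold lower, and the oxidoreductase genes IAG28_RS04190 and IAG28_RS04215 7.26-fold and 7.11-fold lower. The gene efeB, a peroxidase linked to iron uptake, was 10.2-fold lower (8.47 to 12.3), the neighbours IAG28_RS27085 (putative lipoprotein) and IAG28_RS27090 (membrane protein) 9.02-fold and 8.20-fold lower, and the iron compound-binding protein IAG28_RS21640 7.94-fold lower. IAG28_RS01870, a feruloyl-CoA synthetase, was 9.75-fold lower and IAG28_RS23420, a 2-oxoacid ferredoxin oxidoreductase, 6.16-fold lower. The low level of efeB did not last: it was at 87.6, 8.60, 49.7 and 137 scaled CPM at 24, 36, 48 and 72 h.

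At 48 h against 24 h, 476 genes were at least 4-fold higher and 234 at least 4-fold lower, 14.9% of those that passed the minimum. IAG28_RS11240 was 246-fold higher (95% interval 207 to 294), IAG28_RS18935 209-fold and IAG28_RS26030 115-fold higher. IAG28_RS17530, the secreted serine protease streptogrisin C, was at 77.0 scaled CPM at 24 h and 4678 at 48 h (60.8-fold). The urea amidolyase-related gene IAG28_RS00710 was 78.9-fold higher, the lipase IAG28_RS38960 78.0-fold and the nucleotide sugar dehydrogenase IAG28_RS28735 83.9-fold. rocD, IAG28_RS15680 and cydB were 55.2-fold, 58.6-fold and 49.2-fold higher.

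The genes mftC, mftB and IAG28_RS04220 were at their lowest in the 48 h library. mftC, the maturase that modifies the mycofactocin precursor peptide, was 14.2-fold lower (95% interval 13.0 to 15.5), mftB 17.6-fold and the oxidoreductase IAG28_RS04220 18.6-fold lower, with IAG28_RS04195 14.1-fold and IAG28_RS04215 11.5-fold lower. By 72 h mftC was at 720.3 scaled CPM, against 698 at 24 h, and IAG28_RS04220 at 524 against 588. IAG28_RS01870 was 23.8-fold lower at 48 h, the sugar nucleotide dehydrogenase IAG28_RS01960 (UDP-glucose or GDP-mannose) 15.9-fold, the trypsin-type protease IAG28_RS21400 16.6-fold, the endopeptidase IAG28_RS23990 14.1-fold and the branched-chain amino acid aminotransferase IAG28_RS36315 10.9-fold. Of the genes past the 4-fold size at 48 h, 67.0% were higher. With total count scaling the split was 393 higher and 306 lower (56.2% higher), and with FPKM 431 and 340 (55.9%).

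At 72 h against 24 h, 661 genes were at least 4-fold higher and 458 at least 4-fold lower, 23.5% of those that passed the minimum. The nucleotide sugar dehydrogenase IAG28_RS28735 was 679.5-fold higher (95% interval 486 to 982) and IAG28_RS28780, a capK-related protein in the same neighbourhood, 246-fold higher. IAG28_RS18935 was 317-fold, IAG28_RS11240 252-fold and rocD 183-fold higher. hypD, a scaffold for assembling the metal centre of nickel-iron hydrogenase, was at 7.17 scaled CPM at 24 h and 1287 at 72 h (179-fold). IAG28_RS00710 and IAG28_RS00700, a biotin carboxylase gene close to it, were 191-fold and 152-fold higher. IAG28_RS17530 reached 11139 scaled CPM and IAG28_RS15680 5317, 145-fold and 142-fold above 24 h.

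Among the named genes, the largest fall at 72 h was the branched-chain amino acid aminotransferase IAG28_RS36315, 193-fold lower (95% interval 144 to 265), followed by IAG28_RS01960 at 121-fold. The aminomethyltransferase gene IAG28_RS36320, a neighbour of IAG28_RS36315, was 114-fold lower, IAG28_RS01870 50.8-fold and IAG28_RS21400 42.3-fold lower. ispH, the last enzyme of the methylerythritol phosphate route to isoprenoids, was 69.1-fold lower and the adjacent farnesyl diphosphate synthase gene IAG28_RS38630 64.0-fold lower. Both had been above their 24 h level at 36 h, with log2 ratios of 0.68 and 0.60. The type I polyketide synthase genes IAG28_RS01515 and IAG28_RS01520 were 46.9-fold and 37.0-fold lower, and whether they belong to spinosyn synthesis was not worked out here. IAG28_RS01345, a nonribosomal peptide synthetase, had a log2 ratio of −5.05 at 72 h after 2.15 at 36 h. Of the genes past the 4-fold size at 72 h, 59.1% were higher, but the split turned to 505 higher and 670 lower with total count scaling, 546 and 649 without the 10 most abundant genes in the totals, and 534 and 743 with FPKM. Which direction held the larger number of genes at 72 h was therefore set by the scaling.

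The 2 later steps between successive times each changed fewer genes at least 4-fold than the first step, 36 h against 24 h (337 genes, 7.08%). At 48 h against 36 h, 76 genes were at least 4-fold higher and 35 at least 4-fold lower (2.33%), and at 72 h against 48 h 84 were higher and 123 lower (4.35%). In the last step mftC had a log2 ratio of 3.84 and IAG28_RS04220, its neighbour, 4.01. Across the 4762 genes, log2 levels at 24 h correlated with those at 36, 48 and 72 h with Pearson's r of 0.859, 0.717 and 0.578 (Spearman's rho 0.847, 0.710 and 0.576). The correlation was 0.928 between 36 and 48 h (rho 0.920), 0.912 between 48 and 72 h (rho 0.903) and 0.776 between 36 and 72 h (rho 0.765). These are correlations across genes, which are not independent replicates.

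Ribosomal protein and tRNA synthetase genes, which serve translation, were lower as groups after 24 h. The 60 ribosomal protein genes had a median log2 ratio of −0.53 at 36 h, −0.81 at 48 h and −0.58 at 72 h, at percentiles 0, 0 and 0.110 of matched lists. rpsA was at 3533 scaled CPM at 24 h and 2056 at 48 h. Against that direction, 6 ribosomal protein genes lying together were at least 4-fold higher at 48 and 72 h. Among them, the second S18 gene IAG28_RS18735 went from 0.380 scaled CPM at 24 h to 125 at 48 h, the L31 gene IAG28_RS18760 from 0.272 to 92.3 and the L28 gene rpmB (IAG28_RS18750) from 0.109 to 71.3. rpmB rested on 2 counts at 24 h, and its fold of 656 at 48 h had a 95% interval of 181 to 5431. The 22 tRNA synthetase genes had medians of −0.44, −0.77 and −0.72 (percentiles 0.490, 0.220 and 0.940). Of these, lysS had a log2 ratio of −1.95 at 72 h and the isoleucine gene IAG28_RS07330 −1.77, while trpS (IAG28_RS20095) was higher, at 2.85. The 4 RNA polymerase core genes had medians of 0.17, 0.20 and 0.56 (percentiles 49.2, 55.5 and 61.4), and those at 48 and 72 h were −0.03 and 0.16 with total count scaling. Within this group rpoB had a log2 ratio of 1.03 at 72 h and the alpha subunit gene IAG28_RS11960 −0.83.

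Energy metabolism moved unevenly. The 6 ATP synthase genes had medians of −0.58, −0.95 and −0.97 at 36, 48 and 72 h (percentiles 1.79, 1.84 and 2.21), with atpD at −0.75 at 72 h. The 5 glycolysis genes had medians of −0.90, −1.12 and −0.96 (percentiles 0.140, 0.860 and 2.78). The enolase gene IAG28_RS32715 had a log2 ratio of −2.74 at 72 h and gap −0.96, whereas the phosphofructokinase gene IAG28_RS24050 was higher, at 1.52. The 18 respiratory chain genes had medians of 0.20, −0.48 and −0.62 (percentiles 64.3, 6.97 and 2.79). The complex I gene nuoL was at −0.70 at 72 h and the cytochrome c oxidase gene IAG28_RS23955 at −1.57, against 6.91 for cydB and 4.56 for the oxidase gene ctaD. The 7 tricarboxylic acid cycle genes had medians of −0.50, −0.52 and −0.15 (percentiles 5.37, 17.2 and 41.5). sucC and sucD, the subunits of succinyl-CoA ligase, had log2 ratios of −2.71 and −2.48 at 72 h, and the aconitase gene acnA 0.32.

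The lists of iron and siderophore genes, of polyketide and peptide synthases and of rhamnose supply held the lowest medians at 72 h. The 16 polyketide and nonribosomal peptide synthase genes had medians of −0.72, −1.14 and −2.25, and at 72 h 8 of them were at least 4-fold lower and 3 at least 4-fold higher. Of the 8 lower genes 7 are neighbours, so the list holds fewer separate observations than members. Among these 7 the polyketide synthase gene IAG28_RS01515 went from 796 scaled CPM at 24 h to 17.0 at 72 h. The nonribosomal peptide synthetase gene IAG28_RS02415 went the other way, from 1516 to 19132 at 36 h and 8203 at 72 h, and IAG28_RS28375 from 143 to 1575 at 72 h. The list's percentiles were 0.0700, 0.0200 and 0. All 4 genes of dTDP-rhamnose supply, which makes an activated deoxysugar, were at least 2-fold lower at 72 h. Their medians were −1.16, −1.50 and −2.08 (percentiles 0.920, 0.970 and 0.590), with rfbD at −2.48 and rfbB at −2.39 at 72 h. The 9 acyl-CoA supply genes had medians of −0.46, −0.31 and 0.08 (percentiles 4.76, 26.0 and 51.0), the last turning to −0.30 with total count scaling. In this list the biotin carboxylase gene IAG28_RS00700 had a log2 ratio of 7.04 at 72 h, mce, the methylmalonyl-CoA epimerase, 1.84 and the biotin carboxylase gene IAG28_RS27785 −0.23. The 5 iron and siderophore genes had medians of −2.70, −2.05 and −2.51 (percentiles 0.0100, 0.0800 and 0.200). At 36 and 48 h 3 of the 5, which lie close together, were at least 2-fold lower, and at 72 h 4 were. Of those 3, sbnA was at 154 scaled CPM at 24 h and 8.18 at 36 h, and the siderophore synthesis gene IAG28_RS00630 at 108 and 15.8. The iron-linked genes efeB and IAG28_RS21640, named above for their fall at 36 h, are not in this list. Their log2 ratios at 72 h were 0.64 and −0.58, so the list's median does not stand for all iron genes.

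Phosphate and nitrogen genes and secreted hydrolases held the highest medians at 72 h. The 13 phosphate and nitrogen genes had medians of 0.78, 1.19 and 1.61 (percentiles 98.8, 99.4 and 99.7), and at 72 h 9 were at least 2-fold higher and 0 at least 2-fold lower. With no expression minimum the 72 h median was 0.23. narH, a subunit of respiratory nitrate reductase, had a log2 ratio of 3.75 at 72 h, the glutamine synthetase gene glnA (IAG28_RS23770) 2.75 and the phosphate-binding protein gene pstS 1.68. The 9 hydrolase genes had medians of 0.64, 1.05 and 1.58 (percentiles 94.9, 97.3 and 98.7). Here the glycosyl hydrolase IAG28_RS35105 had 3.51 at 72 h and the lipase IAG28_RS38960 6.20, and 1 lipase was at least 2-fold lower. The 11 sugar transport genes had medians of 0.41, 0.49 and 0.64 (percentiles 89.7, 87.6 and 90.7), and 0.25 at 72 h with total count scaling. At 72 h ptsP was at 2.92 and the transporter gene IAG28_RS09055 at −2.47. The 18 amino acid and peptide transport genes had medians of −0.22, 0.12 and −0.07 (percentiles 13.4, 66.4 and 42.8), that at 48 h turning to −0.11 with total count scaling. The permease genes IAG28_RS25965 and IAG28_RS37095 went apart, with log2 ratios of 3.52 and −2.73 at 72 h.

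Stress and regulatory genes gave mixed groups. The 27 chaperone genes had medians of −0.35, −0.81 and −0.67 (percentiles 2.00, 0.120 and 1.53). The main chaperonin gene groL (IAG28_RS17625) was at 27791 scaled CPM at 24 h and 8353 at 48 h, while the ClpC gene IAG28_RS12770 and the dnaK gene IAG28_RS26480 were higher, with log2 ratios of 4.95 and 4.15 at 72 h. The 17 oxidative stress genes had medians of −0.07, −0.00076 and 0.12 (percentiles 37.2, 54.8 and 62.0), the 48 h value turning to 0.02 with median-of-ratios scaling and the 72 h value to −0.27 with total count scaling. In it the catalase-peroxidase gene katG had 1.04 and the thioredoxin reductase gene IAG28_RS37155 4.06 at 72 h. The 27 sigma factor genes had medians of 0.41, 0.49 and 0.44 (percentiles 96.8, 95.4 and 87.9), but 0.05 at 72 h with total count scaling. The SigB gene IAG28_RS24405 had 1.74 at 72 h, the SigA gene IAG28_RS24485 1.08 and the sigma factor gene IAG28_RS11005 −3.82. The 10 development and sporulation genes had medians of 0.69, 0.45 and 0.39 (percentiles 96.6, 84.7 and 74.5), and that at 72 h was −0.0022 with total count scaling. The WhiB-type regulator genes IAG28_RS11665 and IAG28_RS20630 had log2 ratios of 2.36 and 2.51 at 72 h.

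The medians of cell division, repair, other defence and mobile element lists lay between −0.48 and 0.11. The 17 cell division and wall genes had medians of −0.29, −0.34 and −0.48 (percentiles 8.48, 21.1 and 13.0), with ftsZ at 1.13, ftsE at −2.92 and murA at −2.21 at 72 h. The 28 recombination and end joining genes had medians of −0.18, −0.09 and −0.20 (percentiles 18.5, 44.2 and 32.0). Within it 5 genes were at least 2-fold higher and 4 at least 2-fold lower at 72 h. The Ku gene IAG28_RS36115 went from 6.68 scaled CPM at 24 h to 104 at 72 h and ligD from 31.1 to 138. The lexA genes IAG28_RS24280 and IAG28_RS27735 went apart, with log2 ratios of 1.56 and −2.76. The 8 restriction-modification and toxin-antitoxin genes had medians of −0.12, −0.26 and −0.06 (percentiles 36.9 at 36 h and 54.0 at 72 h), with the Mrr-type gene IAG28_RS19370 at −3.71 and the antitoxin gene IAG28_RS11430 at 1.98 at 72 h. Of 85 mobile element genes 15 passed the minimum, with medians of 0.11, −0.05 and −0.14 (percentiles 66.1, 46.6 and 40.3), and that at 36 h turned to −0.03 with total count scaling. Their 72 h median was −1.13 with a minimum of 50. The prophage helicase gene IAG28_RS03630 had a log2 ratio of −1.64 at 72 h and the integrase gene IAG28_RS06295 2.95.

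**Figure D3:**
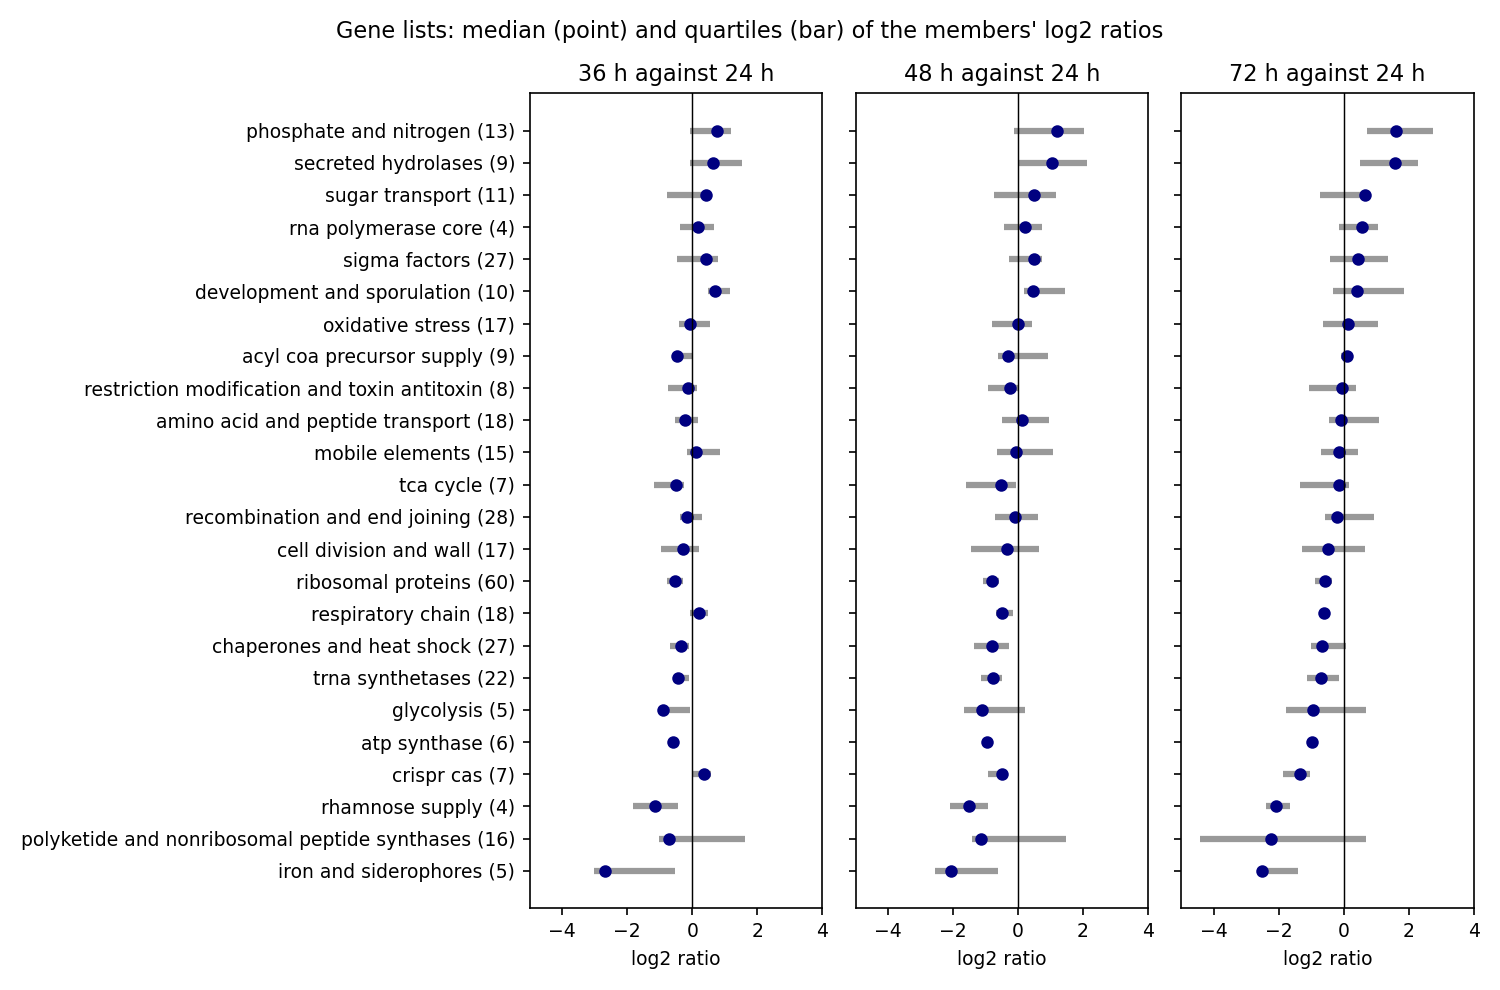
Median (point) and quartiles (bar) of the members' log2 ratios to 24 h for 24 gene lists, with panels for 36, 48 and 72 h and the number of members that passed the minimum in brackets. Phosphate and nitrogen genes lie highest at 72 h (median 1.61, or 0.23 with no expression minimum) and iron and siderophore genes lowest (−2.51), and with total count scaling the medians of acyl-CoA supply, oxidative stress and development at 72 h, of RNA polymerase core and amino acid and peptide transport at 48 h and of mobile elements at 36 h turn below 0, while that of oxidative stress at 48 h turns above 0 with median-of-ratios scaling.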

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

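The cas ratio with nothing added, the median of all 8 cas genes and the lists with all name matches kept were chosen after seeing the data, and every other alternative was planned before the data were examined. Leaving out replicates was not possible with 1 library per time point, and no paired analysis was possible because the time points share no numbered replicates. Cas3 at 36 h turned from 0.14 to −0.0026 with total count scaling and −0.0025 with FPKM, since both leave out the TMM factor. The median of the 6 named cas genes was 0.11 and 0.12 at 36 h, −0.91 and −0.91 at 48 h and −1.95 and −1.97 at 72 h with total count scaling and with FPKM. It was −0.79 at 48 h and −1.90 at 72 h without the 10 most abundant genes, and −0.58 and −1.34 with a pseudocount of 5. With all 8 genes of the locus it was 0.0064, −0.93 and −1.71, and at 36 h these 8 gave −0.13 with total count scaling. Only the 6-gene median stayed above 0 at 36 h under each scaling, while both stayed below 0 at 48 and 72 h. A 2-fold size gave 1253, 2001, 2408, 677 and 788 genes and an 8-fold size 114, 296, 512, 23 and 62 for 36, 48 and 72 h against 24 h, 48 h against 36 h and 72 h against 48 h. The other 8 alternatives kept these counts at 233 to 403, 511 to 797, 822 to 1277, 75 to 142 and 155 to 234. Pearson's r ran from 0.786 to 0.947 for 24 and 36 h, 0.549 to 0.897 for 24 and 48 h, 0.338 to 0.842 for 24 and 72 h, 0.883 to 0.973 for 36 and 48 h, 0.634 to 0.918 for 36 and 72 h and 0.859 to 0.966 for 48 and 72 h over pseudocounts, filters and FPKM. Of the list medians under alternatives, 547 stayed inside the 95% range from resampling a list's members, which is wide for small lists, and 44 left it, 17 of these with FPKM and 15 with total count scaling. Depth limits genes such as cas2, with 47 counts at 72 h.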

Other observations

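All tests and groupings in this part were chosen after the results were seen. Part of the changes lay in runs of neighbouring genes, taken here as at least 5 adjacent genes that were all at least 4-fold higher or all at least 4-fold lower. There were 22 higher and 14 lower runs at 72 h against 24 h, and at most 1 of each in 100 shuffles of the gene order. They held 168 of the 661 higher genes and 115 of the 458 lower genes. A shuffle treats neighbours as independent, so it shows only that changes were grouped along the chromosome. With total count scaling there were 18 higher and 20 lower runs. A run of 18 genes from IAG28_RS27925 to IAG28_RS28010 with the subunits and maturation genes of a nickel-iron hydrogenase had a median log2 ratio of 3.34 at 48 h and 5.40 at 72 h. Its large subunit gene IAG28_RS27995 went from 9.24 to 876 scaled CPM and hypB from 3.69 to 350.4. The 5 nitrate reductase and transporter genes from narI to IAG28_RS20335 had a median of 3.58 at 72 h. The 7 genes with shc, the squalene-hopene cyclase of hopanoid synthesis, and hpnH, hpnD and hpnC had a median fold of 31.9, with shc at a log2 ratio of 5.44. The run with the urocanate hydratase gene IAG28_RS09995 and hutH, enzymes of histidine breakdown, had 4.32, and the ergothioneine genes egtA, egtB, egtC and egtD lay between 2.00 and 2.27, but between 1.61 and 1.87 with total count scaling, which ends that run. The largest rise of a run was that of 11 genes from IAG28_RS28735 to IAG28_RS40260, which include a sugar transferase (IAG28_RS28745) and a nucleotide sugar dehydrogenase, with a median of 8.63.

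The 8 genes from IAG28_RS18735 to IAG28_RS18770 joined ribosomal protein genes for S18, S14, L33, L28, L31 and L32 with the response regulator gene IAG28_RS18770 and a P47K-family gene, IAG28_RS18755, which went from 0.652 scaled CPM at 24 h to 539 at 72 h. Their median was 1.26 at 36 h, 5.55 at 48 h and 5.74 at 72 h, and the last was also 5.74 with the 1 gene at 0 set to the floor of 3 counts. The other S18 gene, IAG28_RS14290, went from 361 to 147. Among lower runs, 22 genes from IAG28_RS01870 to IAG28_RS01980 had a median of −3.20 at 36 h and −5.91 at 72 h, and 8 genes from IAG28_RS01510 to IAG28_RS39900, of which 7 are polyketide synthases whose product was not worked out here, had −0.94 at 36 h, −1.37 at 48 h and −4.47 at 72 h. The 9 genes from IAG28_RS38605 to IAG28_RS38645 with ispH were at 0.23 at 36 h and −5.98 at 72 h, and the 9 genes from IAG28_RS01315 to IAG28_RS01355 with peptide synthetases at 2.11 at 36 h and −4.66 at 72 h.

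The 584 adjacent genes from IAG28_RS28950 to IAG28_RS32110, over 804 kb, held 9 counts in the 4 libraries, while the next longest stretch of such genes had 28 and the lowest 100 adjacent genes elsewhere held 65544 counts. The limit of 10 counts per gene was picked after looking, and limits from 3 to 100 gave 519 to 590 genes. Of its genes 1.03% lay in runs of 3 lengths that recur, so reads shared with copied runs of that kind do not account for the span. Gene lengths on the 1 chromosome record were compared and not sequences, so reads shared with other kinds of copy were not tested. The span had 0.0141 counts per kb, against a 5th percentile of 28.1 for other genes. The span was picked for its low counts, so a value below that percentile alone does not test whether the region is present but silent. The lowest 100 adjacent genes elsewhere were picked in a like way and still held 65544 counts. These values argue against a silent region with the background counts seen elsewhere. Absence from the sequenced strain may explain the 9 counts. This cannot be told apart from a region with no background counts at all, or from one left out of alignment or counting, which give the same counts. No test here decides on a biological explanation.

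Outside that span, 61 genes lay in runs of 3 neighbours whose lengths recur elsewhere, and 32 of them (52.5%) had no count in any library, against 0.954% of 6915 other genes. The run length of 3, and the share counted as high, were picked after looking, and lengths of 2 and 4 gave 6.87% against 0.682% and 71.4% against 1.12%. The other 29 had counts, such as the TraB genes IAG28_RS13360 and IAG28_RS19995 with 87 and 38, so recurring runs were not always at 0. IAG28_RS10215, with 6255 counts, lay beside the ribosomal RNA gene rrf, and several of the 29 lay in such runs. The genes at 0 include both copies of 10 genes, at 523268 to 535679 and 561272 to 573684, with rfbH and a desosaminyltransferase-type gene, of the kind that make and attach deoxysugars. The first copy lies inside the near-empty stretch of 28 genes, at 519924 to 546863. Other genes of that stretch lie in no recurring run, so shared reads as defined here do not account for their low counts. The share at 0 is what discarding reads that align equally well to both copies would give. This is a candidate explanation for the copied genes, while absence of all 32 from the strain cannot be told apart because it gives the same 0. Levels of these genes are therefore unknown, and no biological explanation was tested.

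Along the 8 genes of the cas locus the log2 ratio at 36 h went down from the cas2 end with a rank correlation with position of −0.98, and the correlation was −0.95 at 48 h and −0.71 at 72 h, all against the same 24 h library, but 0.17 for 48 h against 36 h. Among 61 other runs of 8 adjacent expressed genes with gaps up to 200 bp, 1 (1.64%) had as large a correlation at 36 h. The gap limit was picked after looking: with 20, 50 and 100 bp 0 of 2, 5 and 11 runs did, and with 300 bp 2 of 130 did. The cas genes have gaps of 3 bp or overlap, so few of these runs are spaced alike. The order was also seen before it was scored, so how rare it is was not settled. At 72 h 16 of the 61 runs had as large a correlation (26.2%), so nothing sets the locus apart there, and gene length had −0.83. Gene length had a rank correlation of −0.36 with the ratio at 36 h, well short of that of position, and no biological explanation was tested.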
